A study of Mus musculus with 8 samples.

How the data were processed

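The deposited data were droplet single-cell RNA-seq counts (10x Genomics 3' v3) of tumour-bearing mammary fat pads from FVB MMTV-PyMT mice at 7 weeks of age. Per the labels' protocols, mice entered the study at 28 to 30 days, AP20187 was given at 10 mg/kg in 3 doses per week and ABT737 at 25 mg/kg per week by intraperitoneal injection, the pads were digested, live CD45-positive and CD45-negative cells were sorted, and 2 mice were pooled per library. Each of the 8 libraries was deposited as a matrix of whole-number UMI counts per gene and barcode, with no normalization. Per the submitters' processing notes the authors ran Cell Ranger version 4 against mm10, while per the file headers the matrices were written by cellranger version 7.0.1. Which of the 2 versions made the matrices, and the gene annotation used, are not given in the sources used here. The matrices list 32285 features, of which 78 share their symbol with another feature and were kept apart by identifier. The INK-ATTAC and PyMT transgenes are not among the features.

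Libraries were grouped from their labels into INK, WT, ABT and Veh, each in a CD45-negative and a CD45-positive sort, with 1 library per group. Sequencing or collection batches are not given in the sources used here, so any batch cannot be told apart from the arm. The comparisons were INK against WT and ABT against Veh within a sort. WT against Veh, both controls but of different compound and possibly different genotype and day, was computed in the same way as the background.

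Barcodes were kept with at least 200 genes, 500 UMIs and at most 10% mitochondrial UMIs. The mitochondrial limit removed 1479 (INK), 1617 (WT), 1574 (ABT) and 1940 (Veh) of 4712, 4198, 5167 and 6799 CD45-negative barcodes, and 498, 546, 604 and 727 of 3941, 5310, 6870 and 7912 CD45-positive ones. Doublets were scored with Scrublet as implemented in scanpy 1.11.5. Its automatic threshold called 0 to 35 barcodes per library and was judged not to have worked, so the highest scores were removed at 0.8% of barcodes per 1000 barcodes loaded in the matrix, which took 109 to 473 barcodes per library. Cells of each sort were log-normalized, reduced to 2000 variable genes and 30 principal components, joined by 20 nearest neighbours and clustered with Leiden (leidenalg 0.10.2) at resolution 1, without batch integration. A cluster was called by a cell class, written X-like, when at least 3 and at least 50% of the class's markers were higher by a log2 difference of 1 and seen in at least 20% of its cells. 25 marker sets were fixed before the data were examined, as were the comparisons, the tests, 19 gene lists, the rule for named genes and all alternatives not stated to be later. 5 clusters stayed unnamed. In the CD45-positive sort they were cluster 4, with markers of 2 lineages in 72.7% of its barcodes, 15, 16 and 26, and in the CD45-negative sort cluster 15. A limit of 40% on barcodes with markers of 2 lineages, set after the data were examined, kept cluster 4 out of the named classes, and its share of each library is given with the results.

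For shares, exact Clopper-Pearson 95% binomial intervals were computed over all kept cells of a library. For genes, raw UMIs were summed per library and class and divided by the sum over all genes in that class (CPM). Single values have exact 95% Poisson intervals and log2 ratios the exact conditional binomial interval, all for counting error only. A gene list is summarised by the median log2 ratio of members with at least 20 UMIs over the 2 libraries, with an interval from 1000 seeded Poisson redraws and the percentile of the median among 10000 random lists matched on size and mean expression. The fixed lists were senescence genes, targets of ABT737 and relatives, secreted factors linked to senescence (SASP), extracellular matrix, myofibroblastic CAF, inflammatory CAF, MHC class II, cytotoxicity and NK function, NK maturation and residency, inhibitory receptors, interferon response, suppressive and tissue-resident macrophage, inflammatory myeloid, proliferation, milk and alveolar, hormone-sensing, mesenchymal transition, hypoxia and glycolysis, and dissociation stress. A glucocorticoid-responsive list of 13 genes and clock lists of 6 and 3 genes were added after Zbtb16 and Fkbp5 had been seen. Named genes followed a rule of size. Per contrast and in each of the fibroblast-like, luminal epithelial-like, NK-like and macrophage-like classes, it took the 5 highest and 5 lowest by the interval bound nearest 0 among genes with at least 50 UMIs over the 2 libraries, and the same for genes with 1 sign in both contrasts. Mitochondrial, ribosomal, haemoglobin, immunoglobulin and unnamed genes were left out, as were genes under 10% of their CPM in the highest other class. Up to 4 members per list were added without the 10% limit, and those under it are marked in the report or left out. Also added were Cdkn2a, Cdkn2b, Cdkn1a, Ptprc, Epcam and the BCL2 family. 3 of the genes so named are not reported here.

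Shares of cells with a Cdkn2a UMI were also computed with each cell thinned to 1000 UMIs. To set aside differences in cluster mix, fibroblast-like clusters with at least 20 cells in each library were weighted to the same mix, with intervals from 2000 Poisson redraws. Correlations between models were taken across genes with at least 50 UMIs over the 4 libraries of a class, and have no test. Cdkn2a-positive fibroblast-like cells (at least 1 UMI) were compared with negative cells of the same library, up to 3 per positive cell drawn with a fixed seed from the same of 10 depth bins. Sums per library and status were tested with edgeR 4.0.16 (TMM, default filterByExpr, robust quasi-likelihood F-test, library as a block, Cdkn2a left out) at a Benjamini-Hochberg threshold of 0.05. Pairing of the 2 sums comes from their being cells of 1 library, and each of the 4 libraries is 1 replicate.

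The steps were tested on simulated counts with 200 changed genes. For the intervals the counts were Poisson draws without spread between cells or mice, so coverage near 95% followed from the draw. For fibroblast-like cells of INK against WT (11428 genes) the intervals excluded 0 for 80.6, 98.5 and 100% of genes changed 1.5-, 2- and 4-fold, and covered the true value for 95.6%. For ABT against Veh (11840 genes) they excluded 0 for 89.6, 100 and 100% and covered 95.4%. A list raised 2-fold gave medians of 0.97 and 1.01. For the Cdkn2a-positive test (11122 genes, a chosen dispersion of 0.05) edgeR called 7.46, 58.2 and 100% of genes changed 1.5-, 2- and 4-fold, and 1 of 111 calls was an unchanged gene. The changed genes were drawn only from those with at least 500 UMIs, so these rates do not hold for genes with fewer.

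Alternatives planned were doublets kept, a mitochondrial limit of 20%, at least 500 genes and 1000 UMIs, resolution 2, a gate on single cells, another denominator for shares, TMM scaling, a total without mitochondrial and ribosomal genes, other minimum UMIs, and for the Cdkn2a-positive test DESeq2 1.42.0, no filter, no library block, all negative cells and each library left out. Chosen after seeing the data were the removal of barcodes with markers of 2 lineages, the same mix of clusters, and negative cells of the same cluster. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, igraph 0.11.9 and R 4.3.3 were used with random seed 1.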

Results

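Tumour-bearing mammary fat pads of 7-week-old FVB mice carrying the MMTV-PyMT transgene, in which polyoma middle T antigen drives mammary tumours, were profiled by droplet single-cell RNA sequencing. 4 arms were compared. INK mice carried INK-ATTAC, a transgene that makes a caspase 8 fusion from the p16Ink4a promoter and kills the cells using that promoter once the dimerizer AP20187 is given. WT mice lacked the transgene and received the same AP20187 (10 mg/kg, 3 doses per week). ABT mice received ABT737 (25 mg/kg per week), an inhibitor of the anti-apoptotic proteins BCL2, BCL-XL and BCL-W that is used to remove senescent cells, and Veh mice received its vehicle. Live CD45-negative cells (tumour, stroma) and live CD45-positive cells (immune) were sorted separately, and each of the 8 combinations of arm and sort was 1 library made from a pool of 2 mice. No combination had a replicate library. The arms were therefore compared without any test. Every 95% interval given in parentheses covers counting error only, and differences are described as higher or lower in 1 library than in another.

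Total UMIs per library ran from 107593163 (ABT, CD45-negative) to 153399754 (Veh, CD45-negative). After filtering, the CD45-negative libraries held 3043 INK, 2432 WT, 3249 ABT and 4495 Veh cells, and the CD45-positive libraries 3324, 4553, 5905 and 6702 cells. Median UMIs per kept cell differed between the 2 models: 28097 (INK) and 30884 (WT) against 19816 (ABT) and 20003 (Veh) in the CD45-negative sort. Ptprc, which encodes CD45, stood at 3.63 to 9.38 CPM (UMIs scaled by the total of the library or class) in the CD45-negative libraries and at 622 to 716 CPM in the CD45-positive ones. Epcam, an epithelial adhesion molecule, stood at 1411 to 1702 CPM in the CD45-negative libraries. It was still present at 244 to 582 CPM in the CD45-positive libraries, highest in INK. Immune-like classes made up 76.8 to 83.0% of the CD45-positive and 1.65 to 2.33% of the CD45-negative cells.

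The CD45-negative sort was mostly luminal epithelial-like cells, at 73.7% (72.1 to 75.3%) in INK, 69.6% (67.7 to 71.4%) in WT, 56.7% (54.9 to 58.4%) in ABT and 70.1% (68.8 to 71.5%) in Veh. Tumour and normal luminal cells were not separated, and the PyMT transgene is not among the features. Fibroblast-like cells were 24.5% (23.0 to 26.0%) of the ABT library and 10.2% (9.36 to 11.2%) of the Veh library, a log2 ratio of 1.26 (1.11 to 1.41). They were 10.5% in INK and 8.47% in WT, a log2 ratio of 0.30 (0.062 to 0.54), and the WT against Veh log2 ratio was -0.27 (-0.50 to -0.047). With only the non-epithelial, non-immune cells as the denominator, the ABT against Veh log2 ratio was 0.29. Basal epithelial-like cells were 7.46 (INK), 10.2 (WT), 6.03 (ABT) and 9.77% (Veh). Pericyte or smooth muscle-like cells were 0.690% in INK, 2.43% in WT and 1.25% in Veh, and blood endothelial-like cells 2.37% in INK and 3.25% in WT. The share of each class in each library is plotted with its exact binomial interval.

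**Figure D1:**
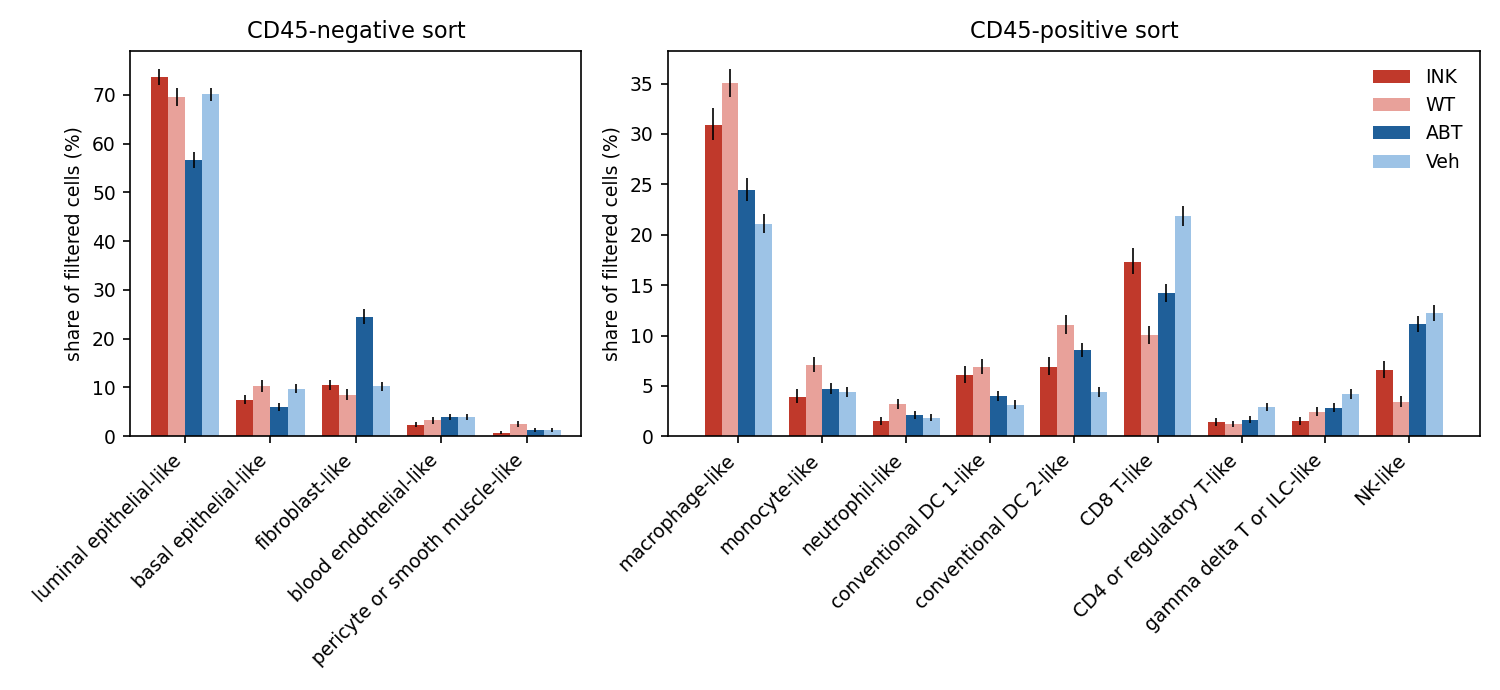
Share of filtered cells (vertical axis, percent) in each named class of the CD45-negative sort (left) and the CD45-positive sort (right). Each bar is 1 library, coloured by arm, with its exact 95% binomial interval; fibroblast-like cells are 24.5% of the ABT library, and NK-like cells 3.45% of the WT and 12.3% of the Veh library.

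Cdkn2a was read first, because INK-ATTAC acts on cells that use its promoter. Cdkn2a encodes the cell cycle inhibitor p16Ink4a and, from another first exon, the p53 activator p19Arf. In the GRCm38 annotation (GENCODE M21) it (identifier ENSMUSG00000044303) lies on the minus strand of chromosome 4 at 89274471 to 89294653, next to the related inhibitor Cdkn2b at 89306299 to 89311039. Its 2 annotated transcripts have 3 exons each, with separate first exons and shared exons 2 and 3, so 3' counts do not separate p16Ink4a from p19Arf. In fibroblast-like cells of the CD45-negative sort Cdkn2a stood at 5.25 CPM in INK (45 UMIs, 3.83 to 7.03) and 9.17 CPM in WT (69 UMIs, 7.14 to 11.6), a log2 ratio of -0.80 (-1.38 to -0.24). It stood at 6.90 CPM in ABT (97 UMIs, 5.60 to 8.42) and 13.5 CPM in Veh (115 UMIs, 11.2 to 16.2), a log2 ratio of -0.97 (-1.38 to -0.57). The 2 control libraries also differed, with WT below Veh at a log2 ratio of -0.56 (-1.01 to -0.12). The share of fibroblast-like cells with a Cdkn2a UMI was 7.55 (4.90 to 11.0%) in INK and 14.1 (9.64 to 19.6%) in WT, at median depths of 25126 and 33832 UMIs per cell. It was 8.17% in ABT and 14.3% in Veh, at 16808 and 17375 UMIs. In luminal epithelial-like cells that share was between 0.223 and 1.05%, at 24016 to 33769.5 UMIs per cell. Thinned to 1000 UMIs per cell, 0 INK, 0 WT, 5 ABT and 5 Veh fibroblast-like cells kept a Cdkn2a UMI, so the thinned share is at its floor.

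The Cdkn2a difference was not spread evenly over the fibroblast-like clusters. Cluster 8, with Cilp, Spon1, Lrrc15 and Postn among its leading genes, held 83.3 (INK), 89.7 (WT), 60.0 (ABT) and 97.0% (Veh) of the cells with a Cdkn2a UMI. That cluster was 33.3 (INK), 37.9 (WT), 23.7 (ABT) and 68.3% (Veh) of all fibroblast-like cells, and in ABT cluster 13, led by Hmcn1 and Penk, was larger at 30.2%. With the clusters weighted to the same mix, the Cdkn2a log2 ratio was -0.75 (-1.30 to -0.23) for INK against WT and -0.062 (-0.47 to 0.32) for ABT against Veh. Within cluster 8 it was -0.88 (-1.50 to -0.29) and -0.29 (-0.75 to 0.16). Within cluster 13 it was 0.38 (-1.80 to 2.75, 5 and 4 UMIs) and 1.94 (-0.10 to 7.86, 27 and 1 UMIs), and clusters 14 and 16 held 0 to 3 UMIs per library. Cdkn2b had log2 ratios of -0.11 (-0.35 to 0.13) and -0.65 (-0.83 to -0.48), the latter 0.19 at the same mix. Cdkn1a, the p53-responsive inhibitor p21, was higher in INK than in WT by 0.70 (0.55 to 0.85) and in ABT than in Veh by 0.33 (0.20 to 0.45), or 0.66 and 0.13 (0.0038 to 0.27) at the same mix. Within cluster 8 the INK against WT log2 ratio of Cdkn1a was -0.40, and in clusters 13, 14 and 16 it was 1.36, 1.74 and 1.31. For ABT against Veh it was 0.32 in cluster 8 and -0.70, 0.33 and 0.54 in clusters 13, 14 and 16.

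**Figure D2:**
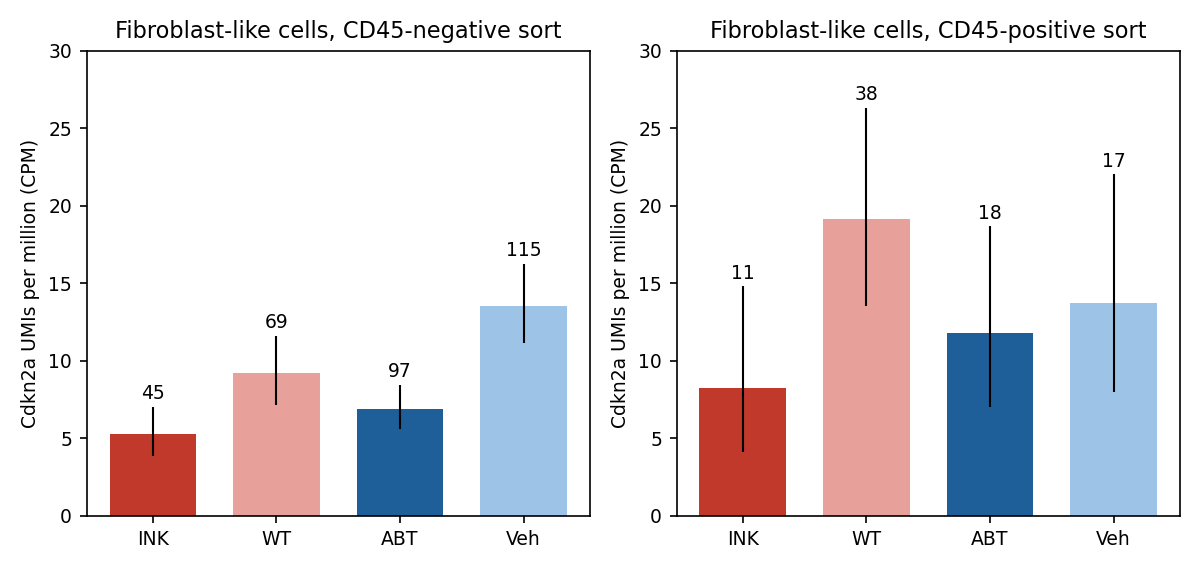
Cdkn2a level (vertical axis, CPM) in fibroblast-like cells of the CD45-negative (left) and CD45-positive (right) sort, 1 bar per library with its exact 95% Poisson interval and the number of UMIs above it. In the CD45-negative sort INK is at 5.25 and WT at 9.17 CPM, ABT at 6.90 and Veh at 13.5 CPM.

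Some genes named by size rest on a single cell. Of 94 genes that the size rule picked over 4 classes, 21 had more than 50% of the UMIs of the higher library in 1 cell, so their counting intervals are too narrow. They were Cxcl5, Ereg, Kcnip4, Mgat4e and Pcdh15 in fibroblast-like cells and Actl6b, Ccl20, Celf6, Dmbt1, Klk6, Mup5, Pate6, Scgb1b27 and Sprr2a3 in luminal epithelial-like cells. In NK-like cells they were Ccl1, Cxcl10, Hspa1b and Slc7a14, and in macrophage-like cells Gpnmb, Slc17a1 and Tas1r1. The comparisons below leave them out. Other genes came near that limit, so their intervals may be too narrow as well. In fibroblast-like cells 1 cell held 44.6% of the WT UMIs of Dpp6 and 46.1% of the Veh UMIs of Top2a, and Hmmr had UMIs in 7 Veh cells. It was 43.5% for Kctd8 (INK) and 44.0% for Sval2 (Veh) in luminal epithelial-like cells, and 44.4% for Frmd5 (WT) in NK-like cells. Other named genes stood under 10% of their CPM in the highest other class, so RNA of other cells is not excluded as a source of their values. They were Acta2, Bcl2 and Epcam in fibroblast-like cells, Areg, Cited1, Foxa1, Pgr and Wnt4 in luminal epithelial-like cells, and Ifi44, Ifit1, Ifitm3 and Oasl2 in macrophage-like cells.

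The comparison of INK with WT asked what differed in the tumours of mice whose transgene is designed to remove cells using the p16Ink4a promoter. Fibroblast-like cells of INK carried less of the contractile and matrix programme of myofibroblastic cancer-associated fibroblasts (CAFs). The smooth muscle actin gene Acta2 was lower, at a log2 ratio of -2.35 (-2.60 to -2.11), the actin-binding gene Tagln was at -2.36 (-2.56 to -2.16), and the matrix gene Tnc (tenascin C) was at -2.79 (-2.89 to -2.70). The collagen gene Col12a1 was at -1.63, the secreted matrix gene Cthrc1 at -1.36 and the fibronectin gene Fn1 at -0.77. The myofibroblastic CAF list had a median log2 ratio of -0.69 (-0.88 to -0.65), with 13 of 15 measured members below 0, at percentile 0 of random lists of like expression. The same median between the 2 controls (WT against Veh) was 0.17. The extracellular matrix list had a median of -0.21 (-0.24 to -0.20), with 26 of 40 below 0, against 0.30 between the controls. Cluster 8 was the largest fibroblast-like cluster of both libraries, and at the same cluster mix these 2 medians were -0.66 and -0.20.

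The secreted factors linked to senescence (SASP list) had a median log2 ratio of -0.16 (-0.23 to -0.10) in INK against WT fibroblast-like cells, with 22 of 34 members below 0. The monocyte chemokines Ccl7 and Ccl2 were at -1.98 and -1.41 and the protease inhibitor Timp1 at -0.90. The inflammatory CAF list had a median of -0.21 (13 of 17 below 0), with Clec3b at -0.32, Cxcl14 at -0.47 and Dpp4 above 0 at 0.57. The control median was 0.91. At the same cluster mix the INK against WT medians were -0.15 (SASP) and -0.31 (inflammatory CAF). The senescence list had a median of -0.095 (-0.19 to -0.0099) at percentile 7.94, and the BCL2 family targets of ABT737 -0.032 (-0.12 to 0.14), with Bcl2 at 0.51. The interferon response list stood at 0.0030 (-0.064 to 0.15), hypoxia and glycolysis genes at 0.042 (-0.059 to 0.14) and dissociation stress genes at 0.13 (0.10 to 0.15). Proliferation genes had a median of -1.65 (-1.92 to -0.87) but came from few cells, with Mki67 UMIs in 9 INK and 6 WT cells. The MHC class II list stood at -0.31 (-0.82 to 0.61), and 76.7% of the INK UMIs of its member Cd74 came from 1 cell. The epithelial marker Epcam was higher in INK fibroblast-like barcodes, at 1.19 (0.90 to 1.49). Among single genes, INK was higher for the transcription factor genes Zbtb16 (2.15, 2.04 to 2.27, UMIs in 246 INK and 99 WT cells) and Tcf21 (4.15, in 11 INK cells and 1 WT cell). Higher too were the cadherin gene Cdh9 (3.29), the B-cell chemokine Cxcl13 (4.21), Krtdap (4.59) and Nexmif (4.81). INK was lower for the adhesion gene Chl1 (-2.47), the potassium channel subunit Dpp6 (-3.59) and the neurotrophin Bdnf (-2.09).

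In the pericyte or smooth muscle-like cells of INK, the extracellular matrix list was lower than in WT, at a median of -0.51 (-0.63 to -0.38) with 28 of 33 members below 0, against 0.54 between the controls. These values rest on 21 INK and 59 WT cells. Members that went the other way included Eln at 2.37 (1.87 to 2.87) and Tnc at 2.14 (1.85 to 2.43). In blood endothelial-like cells the proliferation list stood at -0.46 (-0.68 to -0.21) and the interferon response list at -0.41 (-0.59 to -0.28), the control medians being -1.25 and 0.51.

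In luminal epithelial-like cells, genes of the hormone-sensing lineage were higher in INK than in WT. The list's median log2 ratio was 1.87 (1.59 to 2.12), with 9 of 10 members above 0, and -0.56 between the controls. The progesterone receptor gene Pgr was at 4.39 (3.95 to 4.91), the growth factor gene Areg at 3.87 (3.48 to 4.31), and the transcription regulators Foxa1 and Cited1 at 2.56 and 2.65, with Pgr UMIs in 64 INK and 17 WT cells. Wnt4, a paracrine signal downstream of progesterone, was at 1.54. Pgr, Cited1 and the list member Prlr were among the leading genes of luminal cluster 20, as was the neurexin gene Nrxn3. Areg, Foxa1 and Wnt4 were not. That cluster held 31 INK and 4 WT cells, and the hormone-sensing list was not weighted to the same mix. Nrxn3 (6.84, in 122 INK and 32 WT cells), Kctd8 (4.35), Adarb2 (2.89), the vesicle gene Sv2c (2.42) and Zbtb16 (2.26, in 1432 and 545 cells) were also higher in INK. Milk and alveolar genes were lower, at a median of -0.34 (-0.36 to -0.33) with 13 of 15 below 0 (control median 0.30). Glycam1 was at -1.25, the casein gene Csn1s1 at -0.65 and the milk fat globule gene Mfge8 at -0.49. Luminal cluster 7, led by Csn1s2a, Csn2, Csn1s1 and Wap, made up 7.22% of the luminal epithelial-like cells of INK and 14.5% of those of WT, and the list was not weighted to the same mix. The SASP list stood at -0.29 (-0.38 to -0.25), with a control median of 0.60, the interferon response list at -0.23 (-0.28 to -0.13), mesenchymal transition genes at -0.22 (-0.42 to -0.054), and proliferation genes at -0.15 (-0.17 to -0.10). At the finer clustering resolution of 2.0 the proliferation median turned to 0.31. The imprinted gene Peg10 (-3.31), Tex21 (-3.33), the chromatin protein gene Hmga2 (-2.73) and Meis1 (-0.71) were lower in INK.

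Among CD45-positive cells, NK-like and CD8 T-like cells made up more of the INK library than of the WT library, and myeloid classes less. NK-like cells were 6.62% (5.80 to 7.52%) in INK and 3.45% (2.94 to 4.02%) in WT, a log2 ratio of 0.94 (0.65 to 1.23). CD8 T-like cells were 17.3 and 10.0%, a log2 ratio of 0.79 (0.62 to 0.95). Clusters 2 and 6, which make up that class, had the gamma delta T cell receptor genes Tcrg-C2 and Trgv2 beside Cd8a among their leading genes. The class may therefore hold other cells than conventional CD8 T cells. Macrophage-like cells were 30.9 and 35.0% (-0.18, -0.27 to -0.087), monocyte-like cells 3.94 and 7.07%, conventional DC 2-like cells 6.92 and 11.1%, and neutrophil-like cells 1.47 and 3.18%. The 2 control libraries lay further apart than INK and WT in the NK-like share, at 3.45% in WT and 12.3% in Veh, a log2 ratio of -1.83 (-2.07 to -1.59). WT against Veh log2 ratios of the CD8 T-like (-1.12), macrophage-like (0.73) and conventional DC 2-like shares (1.33) were also larger in size than those of either model. The conventional DC 2-like shares are without the unnamed cluster 4, which shared the leading genes Lyz1, Retnla and Fcrls with conventional DC 2-like cluster 10. A gate on single cells, with a UMI of Ncr1 or Klrb1c and none of the CD3 genes, gave a log2 ratio of -0.15. NK-like cells were 25.7% of the gated barcodes in INK and 11.4% in WT, most of the others being macrophage, monocyte or dendritic cell-like.

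Within NK-like cells of INK, the effector genes did not differ in 1 direction. The cytotoxicity list had a median log2 ratio of 0.0054 (-0.045 to 0.059), with 12 members above and 12 below 0. The chemokine gene Ccl5 (0.55, 0.49 to 0.61) and the granzyme gene Gzma (0.66, 0.59 to 0.72) were higher, Gzmc was lower (-1.88, -1.98 to -1.78), Gzmb was at -0.54, and the pore-forming gene Prf1 was at -0.12 (-0.27 to 0.034). The maturation and residency list had a median of -0.083 (-0.18 to -0.0060), inhibitory receptors -0.047 (-0.23 to 0.075), interferon response genes -0.054 (-0.18 to 0.17), the targets of ABT737 -0.020 (-0.18 to 0.14) and dissociation stress genes 0.064 (0.026 to 0.18). NK cluster 5, led by Gzmc and Xcl1, held most NK-like cells of both libraries. Single genes higher in INK were the kinase gene Camk4 (0.58), the lipid droplet gene Hilpda (0.97), Nmnat2 (1.47) and Zfp53 (0.68). Lower were the Ly49 receptor gene Klra5 (-1.47), Eml6 (-0.99), Dscam (-1.87), Dok6 (-0.90), Zmat4 (-4.22), Frmd5 (-3.25) and Myo1h (-3.20). CD8 T-like cells of INK had a cytotoxicity median of 0.11 (0.077 to 0.14), with Gzma at 1.04 (0.97 to 1.12), Ccl5 at 0.89 (0.85 to 0.94) and the checkpoint gene Lag3 at 0.66. Their proliferation list stood at -0.84 (-0.89 to -0.64), with Mki67 at -1.14. Cycling lymphocytes with markers of CD8 T and NK cells formed the unnamed cluster 15 (Top2a and Kif11 among its leading genes), with 66 INK, 81 WT, 127 ABT and 162 Veh cells, so CD8 T-like proliferation values are without them. Between the controls the same medians were -0.54 and 0.81, and their dissociation stress median in INK against WT was 0.10.

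Macrophage-like and monocyte-like cells of INK carried less interferon-stimulated RNA than those of WT, and macrophage-like cells less cell cycle RNA. The interferon response list had a median log2 ratio of -0.63 (-0.68 to -0.56) in macrophage-like cells, with 24 of 29 members below 0, and -0.78 (-0.85 to -0.59) in monocyte-like cells, with 26 of 28 below 0. The control medians were 0.23 and 0.25, and the median over all genes of macrophage-like cells was -0.14 in INK against WT. The antiviral genes Ifit1 (-2.09, -2.66 to -1.59), Oasl2 (-1.48, -1.72 to -1.26), Ifi44 (-1.62), Ifitm3 (-1.23) and Isg15 (-0.67) were lower in macrophage-like cells, and Ifit2 (-2.16) and Rsad2 (-1.96) in monocyte-like cells. Proliferation genes of macrophage-like cells stood at -0.68 (-0.79 to -0.63), with all 24 members below 0, among them Top2a (-0.90), Ccna2 (-1.37) and Birc5 (-0.95). The control median was -0.092. Inflammatory myeloid genes of macrophage-like cells were higher, at a median of 0.33 (0.32 to 0.35) with 11 of 14 above 0. They included the cytokine genes Il1b (0.33) and Tnf (0.47) and the inflammasome sensor Nlrp3 (0.47). The control median was -0.16. In monocyte-like cells the list members Cxcl10 (-1.06, -1.42 to -0.72) and Ptgs2 (-0.63, -0.73 to -0.53) were instead lower in INK. In neutrophil-like cells Cxcl3 (-1.54) and Ptgs2 (-0.51) were lower, and Il1a was at 0.44 (-0.32 to 1.16). The higher inflammatory RNA is therefore stated for macrophage-like cells only. The mix of macrophage-like clusters differed too. Cluster 1, with Il1a, Ccl3, Ccl4 and Tnf among its leading genes, made up 57.7% of the macrophage-like cells of INK and 42.9% of those of WT, and cluster 3, with Mrc1, Folr2 and Cd163, 19.7 and 29.3%. The macrophage-like values were not weighted to the same mix, so they do not separate a change within clusters from a change in mix. The suppressive and tissue-resident list stood at -0.028 (-0.13 to 0.029) in macrophage-like cells. Other genes higher in INK macrophage-like cells were the glucocorticoid receptor co-chaperone Fkbp5 (2.03, 1.96 to 2.09), the lectin genes Cd209f (1.47) and Cd209g (1.03), the adhesion molecule Vcam1 (1.22), Gbp5 (1.45), Tulp1 (2.91) and Ica1l (0.94). Lower were S100a4 (-1.38), the chemokine Ccl7 (-0.62), the cyclin Ccnd2 (-0.69), the condensin gene Ncapg (-1.63), Mxd3 (-2.28), Atp2b4 (-0.66) and Tppp3 (-1.55).

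**Figure D3:**
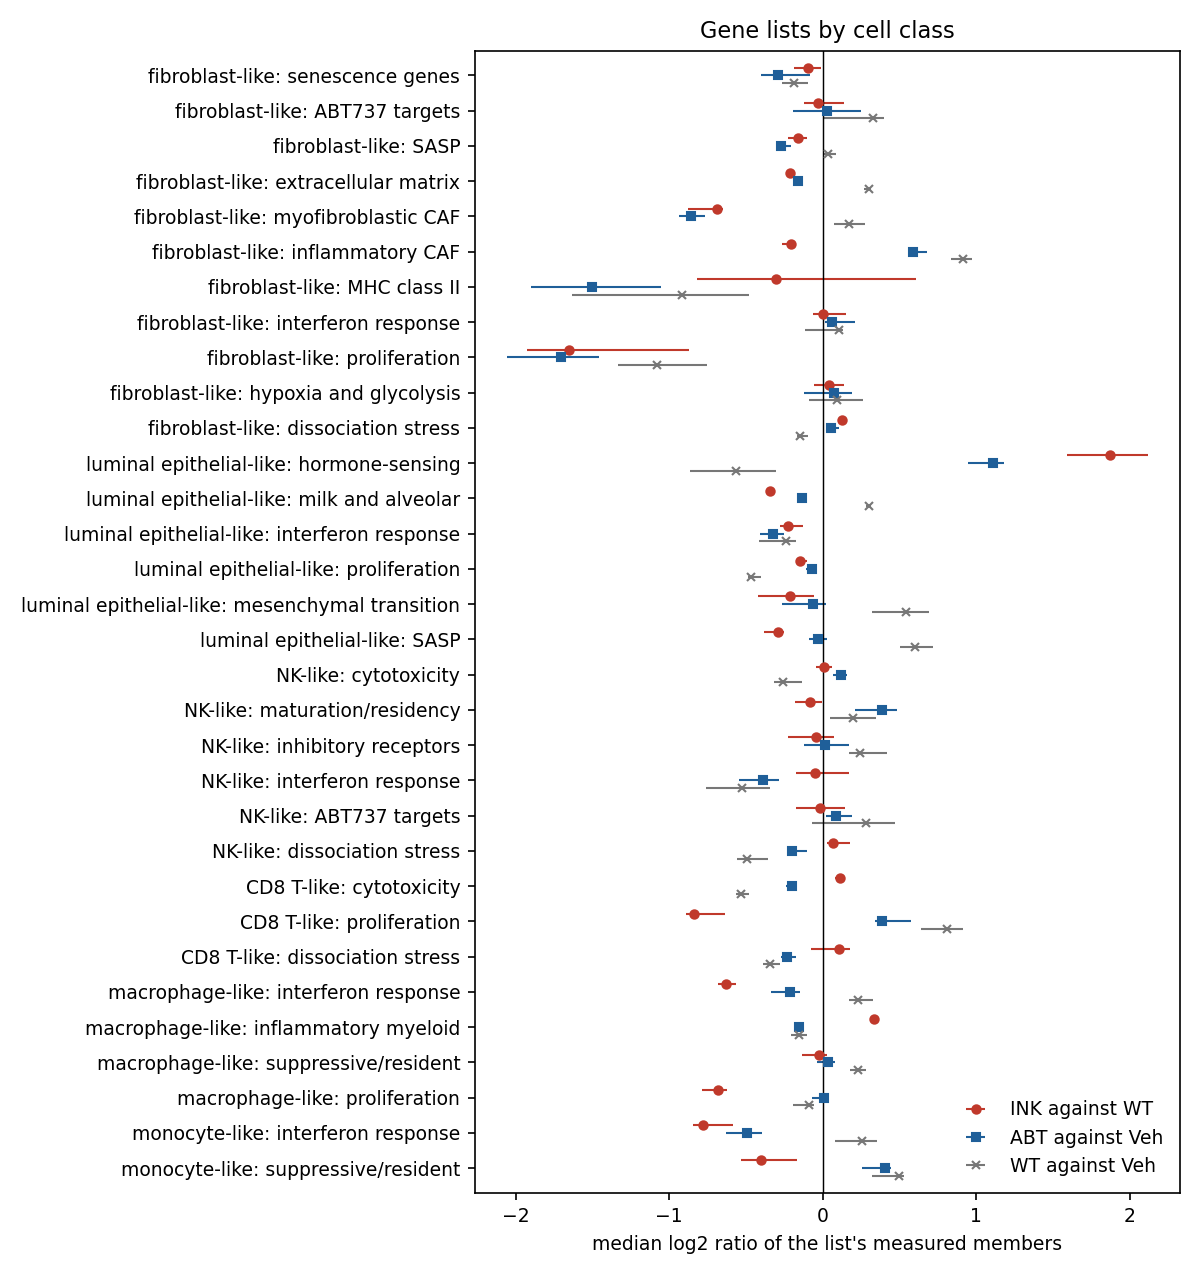
Median log2 ratio of each gene list's measured members (horizontal axis) in 6 cell classes, with 95% counting-error intervals, for INK against WT (circles), ABT against Veh (squares) and the control libraries WT against Veh (crosses). The myofibroblastic CAF list lies at -0.69 and -0.86 in the 2 models and at 0.17 between the controls.

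The comparison of ABT with Veh asked the same of a drug that is used to remove senescent cells. ABT fibroblast-like cells carried less of the myofibroblastic genes and more of the inflammatory CAF genes than Veh ones, and at the same mix of fibroblast-like clusters neither difference remained at that size. The myofibroblastic CAF list had a median log2 ratio of -0.86 (-0.94 to -0.77), with 13 of 16 members below 0, and 0.021 at the same mix. Cluster 8 was the largest fibroblast-like cluster in Veh and cluster 13 in ABT. Tnc was at -2.17 (-2.29 to -2.06), Tagln at -1.40 (-1.53 to -1.28), Acta2 at -0.80 (-0.96 to -0.63), Lrrc15 at -1.14 and the collagen genes Col8a1 and Col11a1 at -1.47 and -1.15. The inflammatory CAF list had a median of 0.59 (0.55 to 0.68), with 12 of 17 above 0, and -0.13 at the same mix. The peptidase gene Dpp4 was at 1.93 (1.81 to 2.05), Clec3b at 1.48, the matrix genes Efemp1 and Dpt at 1.39 and 1.22, and Cxcl14 below 0 at -0.77. The control median was 0.91, larger than that of ABT against Veh.

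The SASP list had a median of -0.27 (-0.31 to -0.21), with 21 of 34 below 0, and -0.039 at the same mix, with Timp1 at -1.53 and the protease inhibitor gene Serpine2 at -1.30. The extracellular matrix list had a median of -0.16 (-0.18 to -0.15) and 0.049 at the same mix, with Fn1 above 0 at 0.56. The senescence list stood at -0.29 (-0.40 to -0.084), with a control median of -0.19. The targets of ABT737 stood at 0.025 (-0.19 to 0.25), with Bcl2 at 0.33. Interferon response genes were at 0.059 (0.015 to 0.21), with Ifi27l2a at 1.14, hypoxia and glycolysis genes at 0.071 (-0.12 to 0.19), with the mitophagy gene Bnip3 at 1.17 and the vasodilator gene Adm at 1.23, and dissociation stress genes at 0.056 (0.029 to 0.10). Proliferation genes had a median of -1.70 (-2.06 to -1.46), all 24 below 0, with Mki67 UMIs in 17 ABT and 12 Veh cells. The MHC class II list stood at -1.51 (-1.90 to -1.05), with 69.0% of the Veh UMIs of Cd74 in 1 cell. The control medians of these 2 lists were -1.08 and -0.92. Epcam was lower in ABT fibroblast-like barcodes, at -2.20 (-2.50 to -1.92). Zbtb16 (2.80, 2.61 to 3.01), Cdh9 (3.82), Tcf21 (4.66), Krtdap (4.23), Cxcl13 (2.79) and the Wnt agonist gene Rspo3 (3.83) were higher in ABT. Chl1 (-2.29), Dpp6 (-2.28), Bdnf (-2.06), Hmmr (-3.71) and Top2a (-3.67) were lower, and the homeobox gene Hoxc10 had 0 UMIs in ABT and 51 in Veh, but also only 2 in INK and 1 in WT, so Veh stands apart. In blood endothelial-like cells the proliferation list stood at -1.30 (-1.47 to -1.03), near the control median of -1.25, and the interferon response list at -0.22 (-0.38 to -0.050). The extracellular matrix list of pericyte or smooth muscle-like cells stood at 0.061 (-0.089 to 0.13).

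Luminal epithelial-like cells of ABT had more hormone-sensing RNA and less casein RNA than those of Veh. The hormone-sensing list had a median of 1.11 (0.95 to 1.18), with 9 of 10 members above 0, Foxa1 at 2.67 (2.36 to 3.01), Pgr at 2.06 (1.85 to 2.29), Cited1 at 1.89 and Wnt4 at 1.46. Areg, the member higher in INK, was at -0.10. Luminal cluster 20 held 51 ABT and 13 Veh cells, and the hormone-sensing list was not weighted to the same mix. Milk and alveolar genes had a median of -0.14 (-0.14 to -0.13), with Glycam1 at -1.20, Csn2 at -0.95, Csn1s1 at -0.93, Csn1s2a at -2.31 (-2.33 to -2.29) and Wap at 0.015. The luminal mix differed, with cluster 9, led by Thrsp and Ceacam10, at 4.29% of these cells in ABT and 12.9% in Veh, cluster 18, with Wap and Lao1 among its leading genes, at 2.55 and 3.87%, and cluster 7 at 7.28 and 7.17%, and the list was not weighted to the same mix. The interferon response list stood at -0.33 (-0.41 to -0.26), with 24 of 27 members below 0, Ifit1 at -1.12 and the regulator Irf7 at -0.81. The control median was -0.24. The SASP list stood at -0.031 (-0.089 to 0.030), mesenchymal transition genes at -0.061 (-0.26 to 0.018) and proliferation genes at -0.072 (-0.11 to -0.049). Nrxn3 (4.93), Kctd8 (3.76), Adarb2 (2.07), Sv2c (2.29), Zbtb16 (1.52) and the transcription factor gene Fezf1 (5.44) were higher in ABT. Meis1 (-1.27) and Sval2 (-3.71) were lower, and Xlr3a had 0 UMIs in ABT and 51 in Veh (36 in INK and 35 in WT).

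Among CD45-positive cells, the ABT library had about as large a share of NK-like cells as Veh and a smaller share of CD8 T-like cells. NK-like cells were 11.1% (10.3 to 12.0%) in ABT and 12.3% (11.5 to 13.1%) in Veh (-0.14, -0.28 to 0.00031), and the gate on single cells gave 0.24. CD8 T-like cells were 14.2 and 21.9% (-0.63, -0.74 to -0.51). Macrophage-like cells were 24.5 and 21.1% (0.21, 0.12 to 0.31), and conventional DC 2-like cells 8.52 and 4.40% (0.95, 0.75 to 1.15). An unnamed cluster with markers of several lineages took 10.3 (ABT), 7.21 (Veh), 2.98 (INK) and 1.54% (WT) of the cells. In NK-like cells of ABT the maturation and residency list, which holds genes of both kinds, had a median of 0.39 (0.21 to 0.48), with 13 members above and 7 below 0, against 0.20 between the controls. The integrin gene Itga2 (0.94) and the receptor Klrg1 (0.69) were higher, and Ltb (-0.74) and the chemokine Xcl1 (-0.82) lower. The cytotoxicity list had a median of 0.12 (0.063 to 0.16), with Ccl5 at 1.11 (1.08 to 1.13), Prf1 at 0.88 (0.80 to 0.95), Gzma at 0.74 (0.72 to 0.77) and Gzmc at -1.30 (-1.39 to -1.21). Most NK-like cells were in cluster 12 (Gzma, Prf1, Eomes) in ABT, with 354 cells, and in cluster 5 (Gzmc, Xcl1, Klrc1) in Veh, with 597. A UMI of a CD3 gene was held by 51.5% (ABT) and 50.9% (Veh) of the cells of cluster 5. The interferon response list stood at -0.39 (-0.54 to -0.29), with a control median of -0.53, inhibitory receptors at 0.016 (-0.12 to 0.17), the targets of ABT737 at 0.087 (0.019 to 0.19) and dissociation stress genes at -0.20 (-0.22 to -0.10). The growth factor gene Angpt1 (1.72), Serpinb9b (1.79), the phosphodiesterase Pde2a (78.9 CPM in ABT and 34.3 in Veh), Elovl7 (1.82), Camk4 (0.51) and Zfp53 (0.54) were higher. Klra5 (-0.72), Eml6 (-0.96), Dscam (-0.93), Dok6 (-0.70), Cmya5 (-1.87), Thrb (-1.90) and Ripply3 (-1.70) were lower. CD8 T-like cells of ABT had lower effector RNA, with a cytotoxicity median of -0.20 (-0.24 to -0.18), 21 of 24 members below 0 and Ifng at -0.97 (-1.24 to -0.71). Their proliferation median was 0.39 (0.34 to 0.57) and their dissociation stress median -0.24.

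In macrophage-like cells of ABT, 4 genes known from tissue-resident macrophages and named by their size were higher. The fixed list, which itself holds Cd163 and Cd209f of these genes, was near 0. The scavenger receptor gene Cd163 was at 1.87 (1.64 to 2.11), the eosinophil chemokine Ccl24 at 2.40 (2.09 to 2.74), and the lectin genes Cd209f and Cd209b at 4.47 (4.03 to 4.97) and 1.93, and the suppressive and tissue-resident list had a median of 0.034 (-0.038 to 0.077). Macrophage cluster 3, with Mrc1, Folr2 and Cd163 among its leading genes, made up 27.2% of the macrophage-like cells of ABT and 17.0% of those of Veh. The values of macrophage-like cells were not weighted to the same mix. The interferon response list stood at -0.21 (-0.34 to -0.15), with 22 of 29 members below 0, Ifit1 at -1.30 and Isg15 at -0.69, and at -0.49 (-0.63 to -0.40) in monocyte-like cells. With doublets kept, the macrophage median was -0.36. Inflammatory myeloid genes stood at -0.16 (-0.17 to -0.13), close to the control median of -0.16, and proliferation genes at 0.0096 (-0.070 to 0.037). Fkbp5 (1.11), Cd209g (3.68), Vcam1 (0.89) and Ica1l (1.37) were higher. The cholesterol hydroxylase gene Ch25h (-1.39), the integrin Itgb8 (-1.08), Olfr110 (-1.24), Fam171b (-1.38), Ccnd2 (-0.67), Ccl7 (-0.57), Atp2b4 (-0.70) and Tppp3 (-0.63) were lower.

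Whether the 2 models shared differences was read across genes, which are not independent replicates. The log2 ratios of INK against WT and of ABT against Veh had a Pearson correlation of 0.237 in luminal epithelial-like, 0.134 in fibroblast-like, 0.130 in macrophage-like and 0.0386 in NK-like cells. Spearman correlations were 0.219, 0.150, 0.166 and 0.0618. No library enters both ratios. The sign was the same in 59.3, 56.1, 59.0 and 51.0% of genes. The median size of the log2 ratio was 0.14 for INK against WT, 0.23 for ABT against Veh and 0.30 for WT against Veh in fibroblast-like cells, and 0.18, 0.11 and 0.30 in macrophage-like cells. In both classes the control libraries differed from each other by more than INK did from WT or ABT from Veh. The median log2 ratio of WT against Veh over all genes was 0.075 in fibroblast-like and 0.24 in macrophage-like cells.

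The comparison with replicates set Cdkn2a-positive against Cdkn2a-negative fibroblast-like cells of the CD45-negative sort, with the 4 libraries as replicates. Cdkn2a-positive cells carried more of the myofibroblastic genes and less of the inflammatory CAF and interferon-inducible genes, most of which did not pass against negative cells of the same cluster. In edgeR's quasi-likelihood test with library as a block, 1094 of 11171 genes passed a Benjamini-Hochberg threshold of 0.05, 400 higher and 694 lower. The positive cells numbered 24 (INK), 29 (WT), 65 (ABT) and 66 (Veh), against 72, 75, 195 and 166 negative cells of like depth. Of the myofibroblastic CAF list, 11 of 15 tested members rose and 0 fell (12 and 0 adjusted over the list alone). Of the inflammatory CAF list, 11 of 17 fell and 0 rose (12 and 2 adjusted over the list alone), and of the interferon response list 11 of 25 fell and 0 rose (15 and 0 adjusted over the list alone). The extracellular matrix list went both ways, with 12 up and 10 down of 40 (17 and 13 adjusted over the list alone), as did the SASP list, with 7 up and 9 down of 34 (9 and 11 adjusted over the list alone). Proliferation genes had 5 of 11 up, senescence genes 2 of 11, hypoxia and glycolysis genes 1 up and 3 down of 13, dissociation stress genes 4 down of 18, the targets of ABT737 1 down of 10, and MHC class II genes 0 of 4. Adjusted over the list alone, 7 proliferation genes were up, 2 senescence genes up, 1 hypoxia gene up and 3 down, 9 stress genes down, and 1 target of ABT737 up and 1 down.

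The rule for this test took, per direction, the 10 genes with the smallest p among called genes that moved alike in every library. The agreement of its 20 genes over 4 of 4 libraries was thus set by the rule and adds no support. Cdkn2b, the neighbouring cell cycle inhibitor, rose by a log2 fold change of 1.94 (SE 0.19, edgeR adjusted p = 4.08e-04), the matrix proteoglycan gene Bgn by 0.66 (SE 0.072, edgeR adjusted p = 3.74e-04) and Timp1 by 0.98 (SE 0.11, edgeR adjusted p = 6.20e-04). Plaat3 (1.19), the kinesin gene Kif26b (1.35), Megf11 (1.75), the splicing factor Rbfox1 (2.80), Chchd10 (1.09) and Pdgfrl (0.96) rose too. The surface antigen genes Ly6c1 (-2.62, SE 0.12, edgeR adjusted p = 4.46e-06) and Ly6a (-1.88) fell, as did the actin-severing gene Gsn (-1.70), the complement gene C4b (-2.13), the hyaluronan precursor enzyme Ugdh (-2.62), the interferon-inducible Ifi205 (-1.79) and Ifi211 (-1.78), the oestrogen receptor gene Esr1 (-2.21), Tshz2 (-2.48) and the angiopoietin receptor Tek (-3.97). Positive cells came mostly from cluster 8. With negative cells from the same cluster only, 27 genes passed (11 higher, 16 lower), 24 of them also among the 1094. Of the genes named above, Cdkn2b, Plaat3, Kif26b, Megf11, Ifi205, Ifi211, Esr1 and Tshz2 passed in that fit. Rbfox1, Chchd10, Pdgfrl, Ly6a, Gsn, C4b, Ugdh and Tek did not. Nor did Bgn (edgeR adjusted p = 0.87), Timp1 (edgeR adjusted p = 0.32) and Ly6c1 (edgeR adjusted p = 0.49). Of the lists, those passing in that fit were 2 of 15 myofibroblastic CAF members (higher), 1 of 40 extracellular matrix members (higher), 2 senescence genes (higher), 2 of 33 SASP members (lower) and 1 dissociation stress gene (lower), and 0 of the inflammatory CAF, interferon response, proliferation and hypoxia lists and of the targets of ABT737. Adjusted over the list alone, the calls in that fit were 5 myofibroblastic CAF members higher, 9 inflammatory CAF members lower, 4 SASP members higher and 6 lower, 1 extracellular matrix member higher and 3 lower, 1 proliferation gene higher, 2 senescence genes higher, 7 dissociation stress genes lower, and 0 of the interferon response, hypoxia and MHC class II lists and the targets of ABT737. From the main fit to that fit the median log2 fold change went from 1.02 to 0.39 (myofibroblastic CAF), -1.81 to -0.44 (inflammatory CAF) and -0.72 to -0.39 (interferon response), but from 1.97 to 1.86 (proliferation, with 10 of 11 members above 0 in both) and -0.23 to -0.25 (dissociation stress), so the lost calls of the last 2 lists do not show that the cluster accounts for them. The proliferation fold changes may rest on few cells. In Veh, Top2a UMIs lay in 13 fibroblast-like cells, with 46.1% of them in 1 cell. The number of cycling cells among the positive ones is not given here. Without the library block 214 passed.

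**Figure D4:**
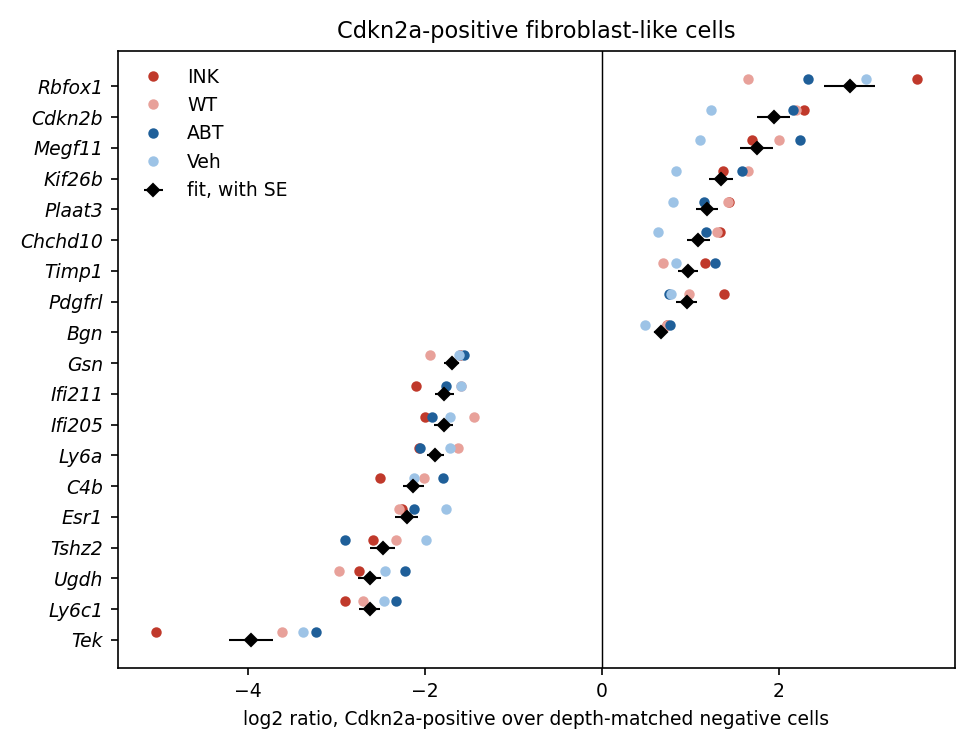
Log2 ratio of Cdkn2a-positive over depth-matched negative fibroblast-like cells (horizontal axis) for 19 of the 20 genes named by the rule. Diamonds with bars are the edgeR estimate and its SE, and each circle is 1 library's ratio of CPM after adding 1 CPM to both sums; Cdkn2b lies at 1.94 and Ly6c1 at -2.62.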

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

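The tests of Cdkn2a in the CD45-positive sort, of the NK-like share among immune classes and between the controls, and of the fibroblast-like share were chosen after their results were seen. The other tests were written down before their own results were seen, but those of the same mix of clusters and of the mixed cluster after other values had been.

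Several values pointed in opposite directions in the 2 models, each with a counting interval that excluded 0 and, for list medians, a size of at least 1.2-fold, and the difference between the models was not tested, since each arm had 1 library per sort. CD8 T cells kill tumour cells through granzymes and perforin. Both clusters of the CD8 T-like class also had gamma delta T cell receptor genes among their leading genes. CD8 T-like cells had log2 share ratios of 0.79 (INK against WT) and -0.63 (ABT against Veh). Their proliferation list stood at -0.84 and 0.39, and at 0.81 between the controls, all without the cycling lymphocytes of the unnamed cluster 15. Conventional DC 2-like cells had ratios of -0.68 and 0.95, and macrophage-like cells -0.18 and 0.21. Conventional DC 2 cells present antigen to CD4 T cells. However, cluster 10, with 938 cells of that class, had 0 of its markers among its leading genes. Its leading genes Lyz1, Retnla and Fcrls also led the unnamed cluster 4 (99 INK, 70 WT, 608 ABT and 483 Veh barcodes). The conventional DC 2-like ratios, also between the controls, are without cluster 4 and could differ with it. Between the controls, WT against Veh, these 3 share ratios were -1.12 (CD8 T-like), 1.33 (conventional DC 2-like) and 0.73 (macrophage-like), each larger in size than in either model. Luminal epithelial-like cells had ratios of 0.083 and -0.31 in the CD45-negative sort (controls -0.011). The suppressive and tissue-resident list in monocyte-like cells stood at -0.40 and 0.40 (0.49 between the controls), with the mannose receptor Mrc1 at -1.48 and 0.39. Not all members went that way, and Ccl2 (-0.75 and -1.01) was lower in both models. Outside the main measurement, macrophage-like cells were present in the sort meant to exclude CD45, at 1.97 (INK), 1.77 (WT), 1.82 (ABT) and 1.51% (Veh). Fibroblast-like cells left in the CD45-positive sort had Cdkn2a log2 ratios of -1.17 and -0.22.

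Cdkn2a, the gene of the p16Ink4a promoter that INK-ATTAC uses, was lower in the fibroblast-like cells of INK than of WT and of ABT than of Veh. In INK a smaller share of cluster 8, with Lrrc15 and Postn among its leading genes, is argued against as the whole of it, since at the same mix of clusters the log2 ratio was -0.75 (-1.30 to -0.23). So is dilution by RNA of other cells in both models, since the fixed fibroblast markers had medians of -0.11 and -0.024. Fibroblast-like cells of the CD45-positive sort gave -1.17 (-2.33 to -0.21) for INK against WT, but its 11 and 38 UMIs lay in 5 of 46 INK and 11 of 58 WT cells, shares with overlapping intervals (3.62 to 23.6% and 9.87 to 31.4%), and the WT against Veh log2 ratio in this sort was 0.46. Whether the 2 sorts of an arm came from the same mice is not given in the sources used here. Removal of Cdkn2a-expressing fibroblasts in INK therefore cannot be told apart from no removal by so few cells, and the spread between mice and the other genotype stay open too. In ABT the value at the same mix was -0.062 (-0.47 to 0.32), with -0.29 within cluster 8 and 1.94 within cluster 13 (27 ABT UMIs and 1 Veh UMI), so fewer cells of cluster 8 could account for the difference, and removal of Cdkn2a-expressing cells cannot be told apart from no removal because the CD45-positive sort held 18 ABT and 17 Veh UMIs (-0.22).

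NK-like cells, innate killers of tumour cells, were a larger share in INK than in WT and about as large a share in ABT as in Veh. The difference of these log2 ratios was 1.08 (0.76 to 1.40). Non-immune cells in the sort are argued against, since among immune classes the difference was 1.11 (0.79 to 1.43). Barcodes of 2 cells stay open in part. With the mixed cluster's barcodes that held an NK marker and no CD3 UMI added (9 INK, 16 WT, 104 ABT and 50 Veh), the difference was 0.87 (0.56 to 1.18). Barcodes of that cluster with a CD3 UMI (86, 36, 441 and 403) were left out, so this value does not cover doublets of NK-like cells that hold CD3. The spread between libraries meant as controls, -1.83 (-2.07 to -1.59), exceeds either model's ratio and could hold all of it. The gate on single cells turned the INK ratio to -0.15, and 65.6 (INK) and 82.4% (WT) of the barcodes it took were macrophage, monocyte or dendritic cell-like, while 59.9 and 67.2% of the cells of NK cluster 5 held a CD3 UMI, as did 51.5 (ABT) and 50.9% (Veh), so the NK-like class of all 4 libraries holds such cells.

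For the fibroblast-like share, higher in ABT than in Veh, the log2 ratio of the blood endothelial-like share was 0.017, and with barcodes of 2 lineages removed that of the fibroblast-like share was 1.30. For the Cdkn2a-positive test, the sums of the 4 libraries can be split within libraries in 8 ways. 1 of the 8, the real split, gave 1094 genes, and the highest other gave 0 in edgeR (123 to 438 genes at an unadjusted p under 0.05), but 8 splits are too few for a share under 0.05. With each of 20 other genes seen about as often in place of Cdkn2a, the count was 0 to 683, with a median of 6.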

How the results depend on the processing

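The removal of barcodes with markers of 2 lineages, the same mix of clusters and negative cells of the same cluster were tried only after the data were seen. Class shares kept their size within the counting interval in 163 of 168 values under an alternative, gene list medians in 562 of 640, and named genes in 2156 of 2377. Of 180 values of the 20 genes of the Cdkn2a-positive test, 162 stayed past the threshold and 18 kept only their direction. Most of these 18 came from the fit with negative cells of the same cluster. The causes of the differences below were not tested, except where cluster mix or the construction of an alternative shows them.

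With doublets kept, the ABT against Veh medians in fibroblast-like cells were -0.32 (SASP), -0.18 (extracellular matrix) and -0.75 (myofibroblastic CAF), that of interferon response in macrophage-like cells -0.36 and that of hormone-sensing genes in luminal cells 1.21. The INK against WT extracellular matrix median was -0.18. Pdk4 in fibroblast-like cells turned from 2.87 to -0.94 (INK), and in luminal cells Csn1s2a to -0.033 (INK) and Areg to 0.20 (ABT), the last 2 from values near 0. With barcodes of 2 lineages removed, fibroblast-like medians were -0.15 (extracellular matrix) and -0.54 (myofibroblastic CAF) for INK, and -0.31 (SASP) and -0.20 (extracellular matrix) for ABT. Reversed genes were Mgat4e in fibroblast-like cells (1.07, ABT), Scgb1b27 (0.14, ABT), Areg (0.040, ABT) and Csn1s2a (-0.15, INK) in luminal cells, and Hspa1b (-0.28, INK) and Ccl1 (-1.72, INK) in NK-like cells. At resolution 2, Cxcl10 in NK-like cells was -0.089 and the luminal proliferation median 0.31 (both INK). At the same mix of clusters, ABT against Veh values in fibroblast-like cells were -0.062 (Cdkn2a), 0.19 (Cdkn2b), -0.039 (SASP), 0.049 (extracellular matrix), 0.021 (myofibroblastic CAF) and -0.13 (inflammatory CAF), so these differences went with the mix of clusters. TMM scaling gave -0.13 (extracellular matrix, ABT), 0.067 (NK cytotoxicity, INK) and -0.52 (macrophage interferon response, INK), and a total without mitochondrial and ribosomal genes -0.15 (extracellular matrix, ABT). With all list members of at least 1 UMI the hormone-sensing medians were 1.54 (INK) and 0.76 (ABT). The gate on single cells gave NK-like log2 share ratios of -0.15 (INK, reversed) and 0.24 (ABT), and the narrower denominator a fibroblast-like ratio of 0.29 (ABT). Over genes with at least 500 UMIs the correlations between models were 0.240 (fibroblast-like), 0.358 (luminal), 0.0702 (NK-like) and 0.208 (macrophage-like).

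In the Cdkn2a-positive test, whose pairing of sums within a library is the block, 214 genes passed with no replicate block (38 higher, 176 lower). DESeq2 gave 751 (266 higher), no filter 1421, all negative cells 1555 (635 higher), and negative cells of the same cluster 27 (11 higher, 16 lower), with 924 of 1006 genes in the same direction. Leaving out 1 library gave 604 to 927 genes, 174 to 357 higher and 430 to 570 lower. Without ABT the count was 604 and without WT 691, each more than 1.5 times below 1094. INK against WT and ABT against Veh could not each be tested, paired or not, because the arms had 1 library each. A difference shared by the 2 models was not tested. Depth limits single genes: a gene with 50 UMIs over 2 libraries has a wide counting interval, and Cdkn2a itself had 45 to 115 UMIs per library in fibroblast-like cells.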

Other observations

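The glucocorticoid-responsive list and its tests were drawn up after Zbtb16 and Fkbp5 had been seen, and the test of dissociation stress and the intervals of the clock test were added after their results.

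Fkbp5 and Zbtb16, a co-chaperone of the glucocorticoid receptor and a transcription factor that it induces, were higher in INK than in WT and in ABT than in Veh in most cell classes. Fkbp5 lay above 0 in 15 of 15 classes for INK against WT (log2 0.15 to 2.29) and in 15 of 15 for ABT against Veh (0.073 to 1.46), and Zbtb16 in 11 of 13 (-2.03 to 5.53) and 13 of 14 (-3.16 to 3.45). Between the controls, WT against Veh, Fkbp5 lay above 0 in 13 of 15 classes (-0.37 to 1.03) and Zbtb16 in 11 of 12 (-0.21 to 1.87). Classes of 1 library are not independent of each other. The other listed genes, among them Tsc22d3, which encodes the anti-inflammatory protein GILZ (1.40 and 0.96 in fibroblast-like cells), were higher most clearly in stroma. Their medians for INK against WT and ABT against Veh were 0.83 and 0.72 in fibroblast-like (0.076 between the controls), 0.98 and 0.67 in blood endothelial-like (-0.26) and 0.96 and 0.70 in pericyte or smooth muscle-like cells (0.16). They were 0.30 and 0.57 in macrophage-like (0.39), 0.19 and 0.35 in luminal epithelial-like (0.49), 0.18 and 0.57 in basal epithelial-like (0.59) and -0.089 and 0.023 in NK-like cells (0.36).

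Higher glucocorticoid signalling in the INK and ABT mice is a candidate explanation, since the median of the other listed genes lay above 0 in 13 of 15 classes for INK against WT and in 13 of 15 for ABT against Veh. A difference in the time of day at collection stays open. The evening minus the morning arm of the clock genes differed by a middle value over 13 classes of 0.17 (-0.29 to 0.57) for INK against WT and 0.33 (0.030 to 0.52) for ABT against Veh, where the ranges are order-statistic intervals of that middle value and 1 had been written as the size to expect and a size under 0.5 as arguing against it. Both middle values lie under 0.5, but the upper ends lie just above it. 12 of 13 classes had 1 sign for ABT against Veh and 9 for INK against WT, where pericyte or smooth muscle-like cells stood at 2.03 and basal epithelial-like cells at 0.85. Stress of dissociation stays open in part, since its list was set against Zbtb16, 1 gene picked for its size. In fibroblast-like cells the stress list had medians of 0.13 (0.098 to 0.15) and 0.056 (0.029 to 0.10). These lie above 0 but below the 0.83 and 0.72 of the other glucocorticoid-responsive genes there. Between the 2 controls the glucocorticoid-responsive median lay above 0 in 10 of 15 classes, with a middle value of 0.18 against 0.22 (INK against WT) and 0.18 (ABT against Veh), but random lists of like expression were shifted between the controls too. The median lay above the central 95% of such lists in 10 classes for INK against WT, 8 for ABT against Veh and 1 between the controls (basal epithelial-like, with luminal epithelial-like cells at the limit). In conventional DC 2-like cells, for example, it was 0.40 in INK against WT (percentile 100) and 0.18 between the controls (percentile 53.9). Not all classes went that way. CD8 T-like cells in ABT against Veh lay below the central 95%, at -0.16 (percentile 1.8). The lowest class medians were -0.28 (INK against WT) and -0.47 (ABT against Veh). AP20187 was given on the same schedule in INK and WT, so its injection does not separate these arms. Handling and the days of collection, which are not given in the sources used here, stay open. So does injection in ABT and Veh, and corticosterone was not measured.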
